A study of Homo sapiens with 4 samples.

How the data were processed

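Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map binding of the glucocorticoid receptor (GR) in A549 cells, a human lung adenocarcinoma line of alveolar epithelial type. The series holds 4 libraries. Cells of 2 libraries received 100 nM dexamethasone, a synthetic glucocorticoid, and cells of the other 2 received 0.02% ethanol as vehicle; the exposure was 3 hours in all of them, per the series' design text. Per the labels' protocols, chromatin was fragmented by sonication, precipitated with an anti-GR antibody and sequenced as single-end reads after PCR amplification. A peak list was at hand for each of the 2 dexamethasone libraries, and values of the ethanol libraries were not analysed here.

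Each peak list gives the chromosome, start, end, name and score of every peak, and its entries are named as peaks of MACS, a caller that compares local read density with a background. CASAVA, Bowtie, SAMtools and MACS are the tools, and hg19 the genome build, per the submitters' processing notes; their versions, settings and order are not given in the sources used here, nor is the background library used for peak calling. Each deposited list belongs to 1 library and carries its own peak numbering; whether the authors called peaks in each library alone is not given in the sources used here. The deposited score of a peak has no stated scale. In both lists it was never below 50, and 55 peaks of replicate 1 and 134 peaks of replicate 2 shared the value 3100. Scores of this kind from MACS are usually a transformed p-value, and 3100 or more was treated as a level at which strong peaks can no longer be ordered. A score grows with sequencing depth, so differences in score between the libraries, as percentiles or as ratios within pairs of peaks, also hold any difference in depth; ranks within a list do not depend on a common scale. Read counts and sequencing depths are not given in the sources used here, so the depth behind each peak is unknown and no counting interval or detection floor could be given.

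Start positions were converted from BED counting to positions counted from 1. Overlap was counted at a minimum of 1 bp, and the counts were checked against bedtools 2.31.1. Peaks of the 2 lists that touched were merged, and a merged region with peaks from both lists was called a replicated region; where a list had several peaks in a region, the highest score was kept. Chance overlap was measured with 1000 random placements of the replicate 1 peaks within their own chromosomes, with widths kept. Chromosome lengths were taken as the last peak end of either list, because no genome of the build was used here. Unassembled and unmappable stretches were therefore open to random placement, which lowers the chance values. Spacing was measured as the share of regions with another region centre within 10 kb, again against 1000 placements, in which regions could overlap. Clusters were runs of replicated regions whose successive centres lay at most 10 kb apart. Scores of one-to-one overlapping peaks were compared by Spearman's rho and by Pearson's r of log10 scores, each with a permutation test of 100000 resamples and Benjamini-Hochberg adjustment over 7 correlations. Density per chromosome was regions per Mb divided by the value over all chromosomes, with a 95% interval from 2000 bootstrap draws of 1 Mb bins. Peaks are not independent replicates, and with 2 libraries no test measures the spread between cultures. Placement and permutation p-values describe these libraries alone.

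The tests were written for Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. The overlap test, the spacing test and the rank correlation were tested on simulated data, and the other tests were not. In simulated lists in which 60.6% of 12455 replicate 1 peaks were copied into the other list, 60.8% were found to overlap. In 12455 simulated regions with no added neighbours, 7.35% had a neighbour within 10 kb against a mean of 8.34% in the placements. The spacing test was thus slightly conservative for regions spread at random over the same lengths. The simulation had no unmappable stretches, so it cannot show how far these lower the chance values for the real regions. In 14306 regions of which 25.9% were given a neighbour or were one, 31.6% had a neighbour against 9.48% at random. A planted rho of 0.786 across 10000 pairs of simulated values was recovered as 0.785. This checked the rank correlation alone, without peak lists, pairing of peaks or the permutation test.

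The overlap, score correlation and spacing tests within chromosomes, other settings of each and the rule for naming regions were fixed before the data were examined. Displacement by 10 to 100 kb, placement within 1 Mb bins, the setting without scores of 3100 or more, clusters of 5 or more regions, density per chromosome, score ratios and neighbours by score were added afterwards. The rule named the 10 replicated regions with the best mean score rank and the 3 highest-scoring peaks of each list without an overlapping peak in the other; other regions named in the text were chosen after their values were seen, by size. Alternatives covered the overlap rule, stricter score limits, the neighbour window, each list alone and merging of close regions. The planned comparisons with gene positions, with gene lists and with sequence motifs (GR full sites, AP-1, C/EBP and others) need an annotation or a sequence of hg19; these were not used here, so regions are given by position and no gene is assigned to them. The planned comparison of dexamethasone with ethanol was not made.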

Results

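GR is a nuclear receptor that binds DNA after it has bound a glucocorticoid. Its binding sites were mapped by ChIP-seq in A549 cells after 3 hours of 100 nM dexamethasone, in 2 replicate libraries. Replicate 1 held 12534 peaks that covered 16.1 Mb, and replicate 2 held 13954 peaks that covered 17.9 Mb. The median peak was 1167 bp wide in replicate 1 and 1189 bp in replicate 2. The median score was 146 and 147, with the middle 50% from 79.7 to 343 and from 79.4 to 358. The upper tail was higher in replicate 2, with a 95th percentile of 1465 against 1296 and with 159 against 65 peaks at a score of 3100 or more, values that also depend on the unknown depth of each library. Nothing in the labels says whether the replicates came from separate cultures, and the spread between them may be technical.

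The first comparison asked how far GR bound the same positions in both libraries. Of the replicate 1 peaks, 10851 (86.6%) overlapped a replicate 2 peak, and 10882 (78.0%) of the replicate 2 peaks overlapped a replicate 1 peak. Random placement of the replicate 1 peaks on their chromosomes gave an overlap of 1.24% ± 0.094 (SD, 1000 placements), and none reached the observed value (permutation test by placement, one-sided p = 0.001, the smallest that these placements allow). Moving each replicate 1 peak by 10 to 100 kb, which keeps the local density of peaks, gave 4.56% (permutation by displacement, added after the data were seen, one-sided p = 0.001). Merging the lists left 10712 replicated regions, with a median width of 1327 bp, beside 1683 regions seen in replicate 1 alone and 3072 seen in replicate 2 alone. When peak centres had to lie within 100 bp of each other, the share of replicate 1 peaks with a partner was 54.1%.

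Strong peaks were nearly always shared. In replicate 1, all 3761 peaks in the upper 30% by score had a partner in replicate 2. In replicate 2, all 1396 peaks of the top 10% and 99.6% of those in the next 10% had one. In the lowest 10%, with scores from 50 to 59.8 in replicate 1 and from 50 to 58.9 in replicate 2, the shares were 49.9% and 36.2%. Peaks seen in 1 list had a median score of 64.7 in replicate 1 and 69.9 in replicate 2, against 177 and 201 for shared peaks.

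**Figure D1:**
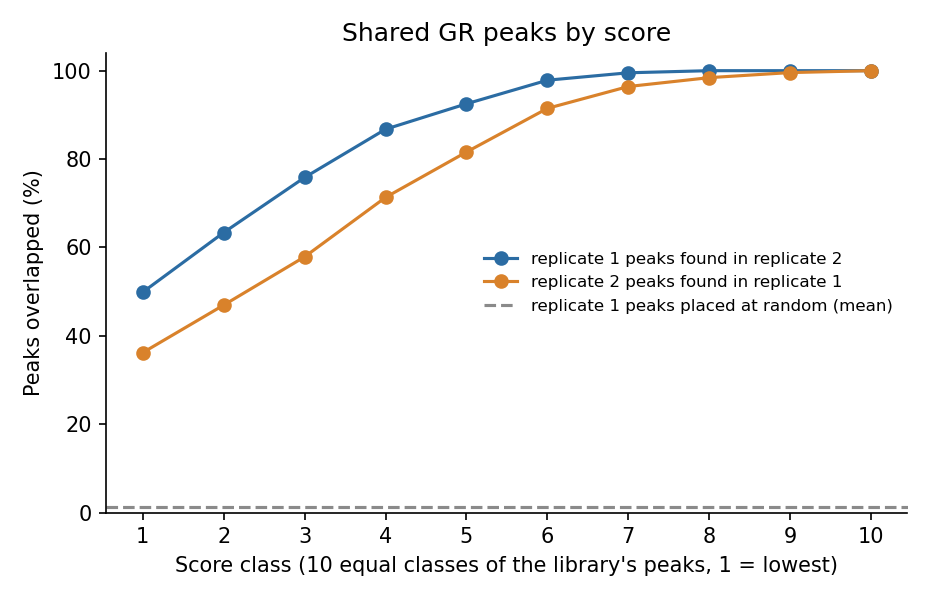
Share of peaks (%, vertical axis) that overlap a peak of the other library by at least 1 bp, by score class (horizontal axis, 10 equal classes of each library's peaks, 1 = lowest); the dashed line is the mean of 1000 random placements, 1.24%. The share climbs from 49.9% and 36.2% in the lowest class to 100% in the top class of both libraries.

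The scores of shared peaks were also compared. Within each list, scores rose with peak width, with a Spearman rho of 0.576 in replicate 1 and 0.648 in replicate 2. Across 10437 one-to-one pairs, scores correlated with a Spearman rho of 0.840 and a Pearson r of 0.888 on log10 scores (permutation test, two-sided, p = 1e-05 for each, the smallest that the resamples allow, and adjusted p = 1e-05). Replicate 2 scored higher in 59.1% of pairs, with a median log2 ratio of 0.14 and an SD of 0.68. Scores differed by more than 2-fold in 14.8% of pairs. Differences of more than 4-fold were uneven in direction, with 101 pairs higher in replicate 2 and 5 higher in replicate 1. The pair that differed most lay on chromosome 12 at 31670869 to 31672596 (hg19, as all positions here), with scores of 50.3 in replicate 1 and 522 in replicate 2. A broad peak on chromosome 9 at 75596531 to 75603793 scored 149 and 1314.

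**Figure D2:**
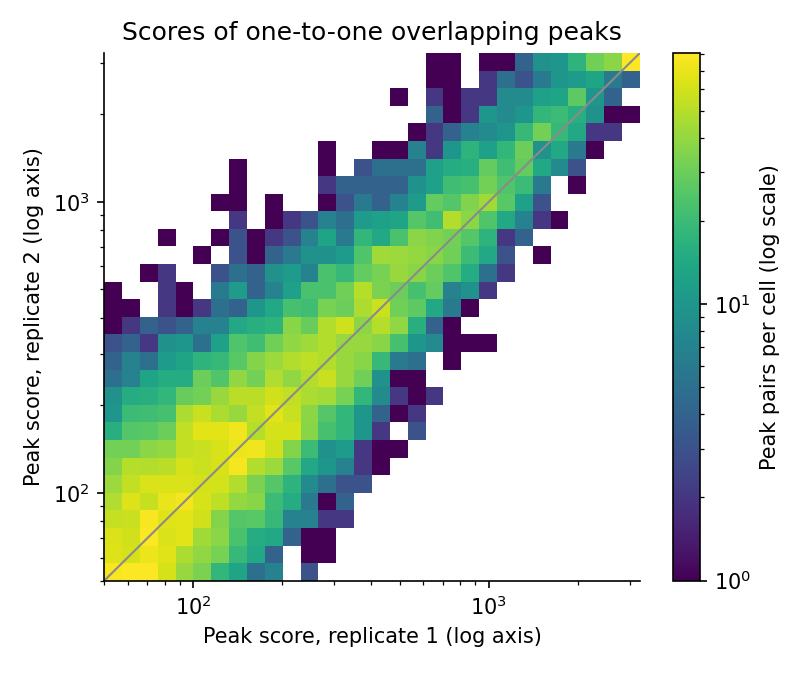
Peak score in replicate 1 (horizontal, log axis) against replicate 2 (vertical, log axis) for 10437 one-to-one overlapping peaks, with colour for the number of pairs per cell (log scale) and a line of equal scores. Pairs far from the line lie mostly above it, where replicate 2 scored higher.

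The strongest GR regions were spread over the genome. In 59 replicated regions on 19 chromosomes the score was 3100 or more in both libraries, with 6 such regions each on chromosomes 10 and 20 and 5 on chromosome 1. From that level upward scores do not order the regions reliably, and a region tied at 3100 in both libraries can rank below one with a lower score in 1 of them. The 10 regions named by mean rank are therefore examples of strong regions and not the 10 strongest. By this rule the first was a region of 1695 bp on chromosome 11 at 20015925 to 20017619, with scores of 3142 and 3157. It was followed by chromosome 20 at 25213499 to 25216449, with scores of 3104 and 3194. That region had 2 other replicated regions within 10 kb, the nearer 4.13 kb away. Next came chromosome 3 at 24000208 to 24001952 and chromosome 6 at 142695787 to 142698120, neither of which had a replicated neighbour within 10 kb. Chromosome X at 109328689 to 109331799, chromosome 6 at 35568763 to 35570724 and chromosome 14 at 69013099 to 69018016 each had 1 such neighbour, at 4.80, 5.09 and 6.51 kb. The list of 10 closed with chromosome 20 at 23019461 to 23021599 and with chromosome 2 at 121691863 to 121695502 and at 121954403 to 121955988. Of these 10 regions, 8 were among the 59 at 3100 or more in both libraries. The other 2 fell below that level in replicate 1, with 3086 for the chromosome 20 region at 23019461 and 2827 for the chromosome 2 region at 121954403.

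The strongest peaks without a partner were less extreme. In replicate 1 they lay on chromosome 4 at 120110454 to 120111606 (score 242), on chromosome 1 at 94496488 to 94497126 (score 216) and on chromosome 12 at 21766597 to 21767781 (score 213). In replicate 2 they lay on chromosome 9 at 75611924 to 75613154 (score 866), on chromosome 2 at 36630447 to 36632261 (score 602) and on chromosome 16 at 88364375 to 88367533 (score 576). The chromosome 9 peak was in the 89.6th percentile of its list, and the nearest replicate 1 peak, 8.13 kb away, was the broad peak with a score of 149.

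Chromosomes 17 and 20 carried the densest GR binding. Chromosome 17 had 6.34 replicated regions per Mb and chromosome 20 had 6.03, against 3.51 over all chromosomes. Relative to all chromosomes this was 1.80 (95% bootstrap interval 1.49 to 2.12) and 1.72 (1.31 to 2.19). Chromosomes 10 (1.26, 1.03 to 1.504) and 12 (1.21, 1.00 to 1.46) were higher by less. Chromosome X had a relative density of 0.482 (0.355 to 0.614), chromosome 13 of 0.586 (0.421 to 0.764), chromosome 4 of 0.680 (0.547 to 0.830), chromosome 21 of 0.580 (0.319 to 0.877) and chromosome Y of 0.196 (0.0816 to 0.339). Each list alone placed these chromosomes on the same side of 1. Lengths counted from the first peak, which leave out the unmapped starts of chromosomes, moved chromosome 13 to 0.692, chromosome 21 to 0.841 and chromosome 22 from 0.979 to 1.46. They took chromosomes 14 and 15 across 1, from 0.863 to 1.04 and from 0.944 to 1.14. Both counts of length kept stretches without peaks inside chromosomes, the longest being 22.9 Mb on chromosome 1, 18.4 Mb on chromosome 9 and 15.8 Mb on chromosome 16. Where such a stretch cannot be mapped, the density of its chromosome is understated. The order of chromosomes after 17 and 20 is therefore not settled. Densities were not corrected for the chromosome copy number of A549.

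**Figure D3:**
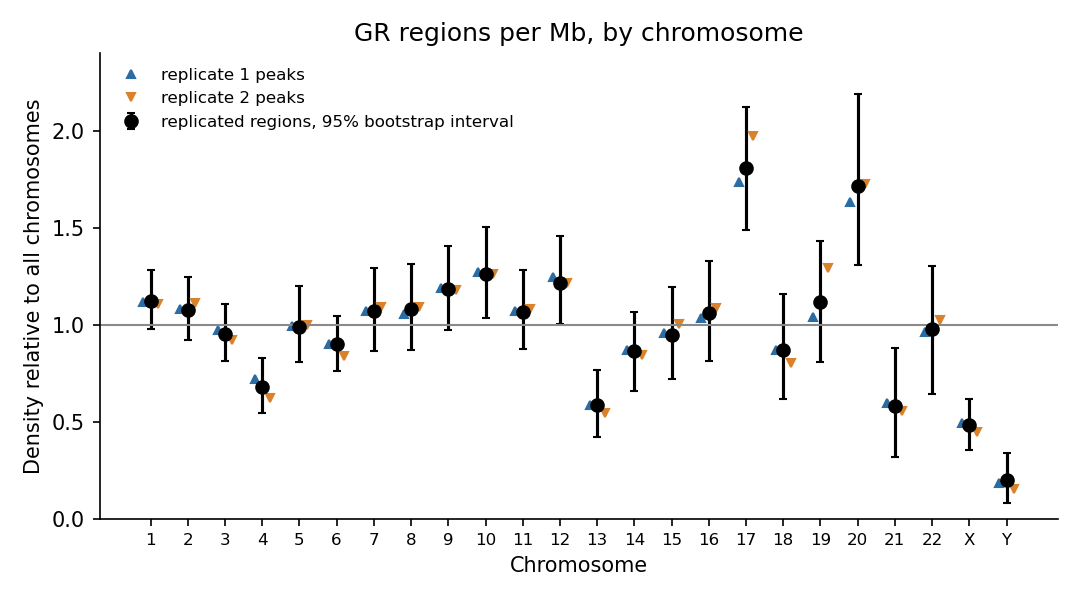
Replicated GR regions per Mb relative to all chromosomes (vertical axis) for each chromosome (horizontal axis), with 95% bootstrap intervals over 1 Mb bins; triangles give the peaks of each library alone. Chromosomes 10, 12, 17 and 20 lie above 1 and chromosomes 4, 13, 21, X and Y below it with their whole intervals.

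The series title concerns clusters of binding around GR sites, and the spacing of GR regions addresses the part that peak positions can show. Replicated GR regions lay close together. Of the 10712 regions, 4591 (42.9%) had another within 10 kb, against 7.23% ± 0.35 (SD, 1000 placements) for random positions (permutation test by placement, one-sided p = 0.001, the smallest possible). The median distance to the nearest other region was 14.1 kb. Within 5 kb the share was 26.8% against 3.69% at random, and within 50 kb it was 71.9% against 31.1% (permutation by placement, one-sided p = 0.001 for each). Regions placed at random within their own 1 Mb bin had a neighbour within 10 kb in 14.7% of cases, a placement added after the data were seen. All 12534 peaks of the replicate 1 list gave 45.8% and all 13954 of the replicate 2 list 48.1%, against 8.39% and 9.47% for random positions within chromosomes.

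**Figure D4:**
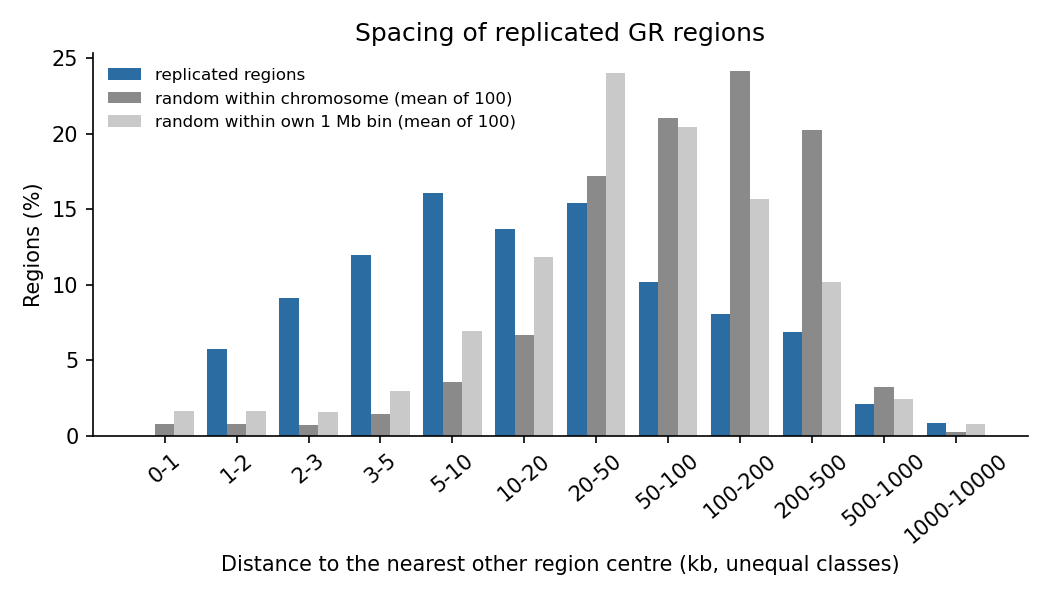
Distribution of the distance from each replicated region centre to the nearest other one (horizontal axis, kb, in classes of unequal width; vertical axis, % of the 10712 regions), beside the means of 100 random placements within chromosomes and within 1 Mb bins. Distances from 1 to 10 kb are more frequent than in either kind of placement.

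Runs of regions with successive centres at most 10 kb apart formed 1853 clusters of 2 or more, beside 6121 single regions. Clusters of 5 or more numbered 78 and held 431 regions, against a mean of 0.029 in random placements and 1.53 in placements within 1 Mb bins (permutation by placement, one-sided p = 0.001 for each). The cluster with the most regions lay on chromosome 1 at 8229353 to 8274372, where 11 regions spanned 45.02 kb. Its scores ran from 52.5 to 2597 in replicate 1 and from 87.4 to 2390 in replicate 2. The next cluster, with 9 regions in 42.5 kb, lay on the same chromosome at 8115848 to 8158346, and its best region ranked 520th of all by mean score rank. In both clusters some adjacent regions lay less than 1 kb apart, such as those ending at 8243417 and starting at 8243954. Clusters were not recounted after regions closer than 1 kb were merged, so adjacent pieces of 1 site may count as separate regions. A cluster of 8 regions on chromosome 12 at 32588294 to 32615134 had median scores of 1003 and 944. Clusters of 7 regions lay on chromosome 21 at 44914017 to 44940523, on chromosome 13 at 95906098 to 95934209, on chromosome 14 at 50432582 to 50476464 and on chromosome 7 at 130564972 to 130589858. Of the 1 Mb bins, the one from 58 to 59 Mb on chromosome 5 held the most replicated regions, 35, followed by 8 to 9 Mb on chromosome 1 with 33 and by 28 to 29 Mb on chromosome 2 and 48 to 49 Mb on chromosome 20 with 29 each.

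**Figure D5:**
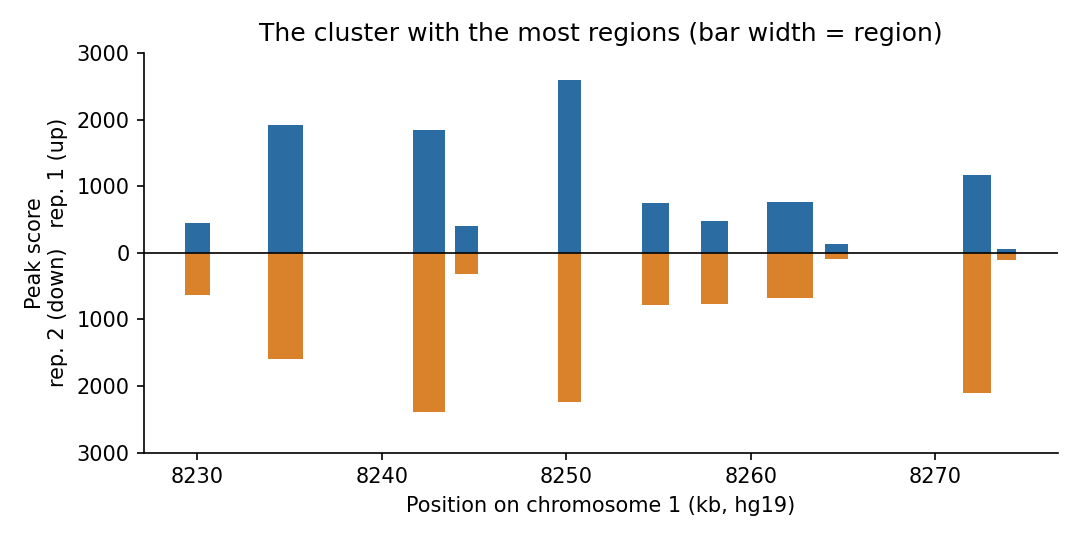
The 11 replicated regions of the cluster on chromosome 1 at 8229353 to 8274372 (horizontal axis, kb, hg19), with bar width for the merged region and bar height for its highest peak score in replicate 1 (upward) and replicate 2 (downward). Of the 11 regions, 4 scored above 1000 in both libraries and the others at most 788 in either.

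The comparison of dexamethasone with ethanol vehicle, which the design implies, was not analysed here, since values were at hand for the dexamethasone libraries only. The peaks above therefore describe where peaks were called with the anti-GR antibody after dexamethasone, and not how far the hormone changed GR binding. Unspecific signal that recurs in both libraries could not be told apart from GR binding.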

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

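Every alternative kept the direction of the overlap, the score correlation and the spacing, and their side of the 0.05 threshold; the tests with peaks moved by 10 to 100 kb, with placement in 1 Mb bins, without scores of 3100 or more, of density per chromosome, of score ratios by chromosome and of neighbours by score were chosen only after the data were seen. The share of replicate 1 peaks with a partner was 83.9% with overlap of at least 50% of both peaks, 84.0% in the top 5000 peaks of each list, 85.7% without chromosome Y and the widest 1% of peaks, 87.5% in the upper 50% of each list and 54.1% with centres within 100 bp. In the settings with the top 5000 or the upper 50%, a partner counted only if it passed the same limit in its own list. The number of replicated regions was 10712, and 5435 in the upper 50% of each list and 4159 in the top 5000. The latter 2 settings start from fewer peaks by construction. With centres within 100 bp, 6784 replicate 1 peaks had a partner, a count of peaks to be set against 10851 with any overlap. The share of regions with a neighbour within 10 kb was 34.9% in the upper 50% of both lists, against 3.78% at random. In the main setting it was 42.9% against 7.23%. After regions closer than 1 kb were merged it was 36.0% against 6.82%. With replicate 2 left out it was 45.8% against 8.39%, and with replicate 1 left out 48.1% against 9.47%. Leaving out a replicate was not possible for the overlap and the score correlation, which need both lists. No paired analysis was possible because values of the ethanol libraries, which share the replicate numbers, were not analysed here. Comparisons with gene positions, gene lists and motifs were not run, nor were their alternatives. Sequencing depth is unknown, so peaks missing from 1 list cannot be read as absence of binding.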

Other observations

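All tests in this part were added after the peak lists had been opened; those of chromosome groups and of the best region per cluster were chosen only after the values they measure had been seen. Strong GR regions had more company than weak ones. Regions in the top 10% by mean score rank had 0.960 ± 0.029 (SEM, 1072 regions) other replicated regions within 10 kb, and those in the bottom 10% had 0.419 ± 0.022 (1071 regions). These SEMs treat regions as independent, although regions that lie close together count each other as neighbours. At least 1 neighbour was present for 61.3% of the top 10% and 31.4% of the bottom 10%. Single regions had a median percentile of 42.6 by score, below the 50 expected of a randomly drawn region. The best region of a cluster of 3 had a median percentile of 84.8, where the best of 3 randomly drawn regions would have 79.4, and for clusters of 5 the values were 94.1 and 87.1. Scores of adjacent regions within 10 kb were only weakly related, with a Spearman rho of 0.105 across 2738 adjacent pairs, against 0.038 ± 0.018 (SD) when scores were permuted within 1 Mb bins (one-sided permutation p = 0.001).

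Peaks seen in 1 library also gathered near replicated regions. Of the 1683 peaks seen in replicate 1 alone, 30.6% lay within 10 kb of a replicated region centre, and of the 3072 seen in replicate 2 alone, 32.8% did. Placement within their own 1 Mb bins gave 10.2% and 11.7% (permutation by placement, one-sided p = 0.001 for each, 1000 placements).

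Why GR regions lie close together was weighed first. Division of one broad site into adjacent peaks does not account for the whole pattern, since 28.0% of regions had their nearest neighbour 3 to 10 kb away, while the highest of the placements within chromosomes gave 5.82% and the highest of those within 1 Mb bins 11.1%. Regional density of callable or open sequence at the scale of 1 Mb does not either: the highest of 1000 placements within 1 Mb bins gave 16.1%, against 42.9% observed. The series title concerns direct GR sites and clusters of binding around them, but direct sites were not identified here. A candidate explanation by score alone is that strong sites bring further binding to their surroundings. The difference of 0.541 neighbours between the top and bottom 10% goes with it. Permuting scores within 1 Mb bins left 0.252 ± 0.030 (SD) (two-sided permutation p = 1e-04, the smallest that 10000 permutations allow). For neighbours 3 to 10 kb away the difference was 0.452 against 0.213. These values do not show whether the strong regions are direct sites. Open chromatin, enhancer domains or transcription at a scale below 1 Mb could give the same values and stay open, and the presence of a GR sequence motif in the strong regions was not tested.

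Why some peaks appeared in 1 library was weighed second. Displaced partners were rare, since at most 8.79% of the peaks seen in 1 list had a peak of the other list within 1 kb. Scores near the limit of the peak caller go with the pattern, since at most 2.82% of the peaks in the upper 50% of a list lacked a partner. A difference in depth or enrichment between the libraries could produce this and was not tested.

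The third pattern was a difference between the libraries by groups of chromosomes, which were chosen because of these values, so the tests describe the pattern and are no evidence for an explanation. Of the peaks seen in replicate 2 alone, 19.6% lay on chromosomes 16, 17, 19, 20 and 22, against 10.6% of those seen in replicate 1 alone, with an odds ratio of 2.06 (Fisher's exact test, two-sided, p = 1.34e-16, adjusted p = 6.69e-16 over 5 tests, too small because neighbouring peaks are not independent). Over all peaks the shares were 16.2% and 14.7%, with an odds ratio of 1.13, and no single chromosome passed (lowest adjusted p = 0.172, Fisher's exact test over 24 chromosomes). The mean log2 ratio of replicate 2 to replicate 1 scores in shared pairs was 0.26 ± 0.021 (SE) higher on these chromosomes than on chromosomes 3, 4, 5, 6, 13, 18 and X. This SE treats peak pairs as independent and does not measure the spread between chromosomes, so it is too small for this comparison. The medians were 0.21, 0.38, 0.35, 0.22 and 0.25 on chromosomes 16, 17, 19, 20 and 22, all above those of the second group, which ran from -0.06 on chromosome 13 to 0.17 on chromosome 5. Chromosomes 11, 12 and 15, in neither group, had 0.20, 0.21 and 0.22. A library difference that follows GC-rich chromosomes and a difference between the cells of the replicates cannot be told apart here, since GC content was not measured and each replicate is 1 library.

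Peaks wider than 5 kb, a limit chosen after the widths were seen, numbered 4 in replicate 1 and 17 in replicate 2, and 5 of the latter had no partner. These counts compare 1 library with 1 library, and width can depend on the unknown depth. The widest of these were on chromosome 11 at 65265888 to 65275845 (9958 bp, score 123) and at 65188204 to 65197147 (8944 bp, score 483). Whether these broad peaks are GR binding or unspecific signal, such as that of strongly transcribed loci, was not tested. The top 10% of regions lay within 2 Mb of the longest peak-free stretch of their chromosome in 4.20% of cases and other regions in 3.73% (Fisher's exact test, two-sided, p = 0.447).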
